A study of Mus musculus with 2 samples.

How the data were processed

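Caudal tissue of wild-type C57BL/6J mouse embryos at embryonic day 8.5 was measured by droplet single-cell RNA sequencing with a 10x Genomics 5′ kit. Per the labels, tissue was pooled and dissociated for 15 min with TrypLE, cells were loaded at about 1500 per µl with over 85% viability, and up to 20000 cells were targeted per library. The labels name 1 group with 2 replicates and list endoderm, mesoderm and ectoderm as cell types. Whether the libraries came from separate pools of embryos, their sequencing dates and the number of embryos are not given in the sources used here.

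The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 6.1.1 on the mm10 genome. The annotation behind them is not given in the sources used here. The lowest total of a barcode was 500 UMIs, so the barcodes had been selected before deposition by a rule that is not given. The features comprised 32286 entries, of which 1 is a custom eGFP sequence. Replicate 1 held 30449 barcodes with 295866003 UMIs and replicate 2 held 18245 barcodes with 150964773 UMIs, with medians of 5842 and 6351 UMIs per barcode. Exact Clopper-Pearson intervals (95%) are given for shares of cells in 1 library, and a count of 0 cells is given with its exact upper bound. Intervals and floors cover counting error only.

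Barcodes with at least 2000 UMIs, at least 1000 genes and at most 10% mitochondrial UMIs were retained, which left 22432 and 13488 barcodes. Doublets were called per library with Scrublet (Scanpy 1.11.5, seed 0) at its automatic threshold, with an expected rate of 0.8% per 1000 barcodes (24.4% and 14.6%). Scrublet marked 1502 (6.70%) and 263 (1.95%) barcodes, far fewer than its expected rates, and these were removed. The 20930 and 13225 remaining cells were scaled to 10000 UMIs and log-transformed. Each gene was centred within each library, divided by its SD over the cells of both libraries and clipped at 10 SD. The 2000 most variable genes among those found in at least 20 cells were used, leaving out T, Sox2, Hox and Cdx genes, the Wnt, FGF and retinoic acid lists, haemoglobin, mitochondrial and Y-linked genes and Xist. Clustering used 40 principal components, 20 neighbours, a graph weighted by shared neighbours and Leiden at resolution 1 (seed 1, leidenalg 0.10.2, igraph 0.11.9). Each cluster took the name of the marker list with the highest mean log2 fold over the other clusters. That mean, taken with a pseudocount of 20 CPM (counts scaled to the class or cluster total), had to exceed 0.3, and at least 3 markers had to reach 20 CPM. A cluster stayed unnamed when another list had more markers among its 10 top genes or when mitochondrial genes led it. Every class name therefore ends in "-like".

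The neuromesodermal compartment comprised the caudal epiblast-like, neural-like and presomitic mesoderm-like cells, since no cluster took the primitive streak name. Its cells were thinned at random (seed 11) to 3500 UMIs, the largest multiple of 500 not above the 20th percentile of their totals, and shallower cells were left out. A cell with at least 1 Sox2 and 1 T UMI after thinning was called double-positive, a cell with 1 of the genes was called Sox2-only or T-only, and the rest were double-negative. Blood-like and endothelium-like cells, thinned alike, gave the background. Odds ratios of detecting both genes carry exact conditional intervals per library. In a second grading, double-positive cells with more T than Sox2 UMIs were called T-biased and those with fewer Sox2-biased. The thinned counts held 0 Sox2-biased cells in replicate 1, so the graded comparison was fitted on unthinned counts, a change made once this was known.

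For tests, the unthinned counts of each class were summed per library (n = 2 libraries per class). They were fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, prior count 2) with library as a block, in 1 fit for all gate classes and 1 fit for all named classes with at least 50 cells in each library. Two-sided p values were adjusted over all 12211 genes tested in the gate classes by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) were derived from the fold change and its F statistic. Sox2 and T were left out of counts and lists because they define the classes. For the comparisons between clusters, 99 genes had been held out of clustering and of naming, of which 94 were tested. Gene lists with at least 3 measured members were tested with limma 3.58.1 by fry, which asks whether the members move on balance in 1 direction, and by camera with an estimated correlation, which compares them with other genes. Both were adjusted over lists and contrasts. The 27 lists cover caudal epiblast and neuromesodermal progenitor, neural tube, presomitic mesoderm, somite, primitive streak, epiblast and pluripotency, epithelial adhesion, epithelial to mesenchymal transition, Wnt, FGF, retinoic acid, Notch, BMP and TGF-beta signalling, Cdx, Hox paralogue groups 1 to 4, 5 to 9 and 10 to 13, cell cycle, glycolysis, dissociation stress, notochord and node, endoderm, blood, endothelium, lateral plate mesoderm, surface ectoderm and neural crest. They share members, such as Cyp26a1 and Wnt3a.

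Lists, markers, filters, gates, tests and the rule for named genes were chosen before the data were examined, whereas the numeric limits for naming clusters were set with the clusters in hand. By that rule, the text names for each gate contrast up to 10 genes per direction with the largest log2 fold change among those past the threshold, changed the same way in both libraries and at a mean of at least 20 CPM in 1 of the classes, leaving out Sox2, T, mitochondrial and ribosomal protein genes, haemoglobins and predicted genes. For genes higher or lower than in both single-positive classes, it takes up to 12. Members of the fixed lists may be named beyond that. Not every gene that the rule takes is named. A fold against a class with 0 counts is given as a bound against a floor of 3 counts over the class's libraries. With 1 to 3 counts the ratio of counts is given with its counting interval. List medians given "with bounds" use these values in place of the fitted ones.

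The pipeline was tested on simulated data with 200 changed genes among 12135. Every gene was drawn with 1 common dispersion, and Sox2-only and T-only cells had the same simulated profile, unlike in the data. It recovered 10.8%, 29.9% and 60.9% of genes changed 1.5-, 2- and 4-fold in double-positive against Sox2-only cells. Against T-only cells it recovered 12.3%, 32.8% and 60.9%. Of the genes simulated as higher than in both classes 43.4% were recovered. False calls numbered 6, 5 and 0 in these tests. Alternatives were DESeq2 1.42.0 with its size factors, RLE scaling, no filter on low counts, no library block, each replicate left out, doublets retained or removed up to the expected rate, at least 4000 UMIs, at most 5% mitochondrial UMIs, resolutions 0.5 and 2, no centring per library, unthinned counts, another thinning seed (12), gates on all cells, a gate of at least 2 UMIs and a fit without double-negative cells. Fits on barcodes with at least or under 0.3% mitochondrial UMIs were added after seeing the data. Correlations between the libraries across genes are descriptions only, since genes are not independent replicates. Intronic reads, read-level files and eGFP were not used here for the comparisons. Chromosomes of 20 genes were read from GENCODE vM21. Further software comprised Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.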

Results

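Single-cell RNA was counted in 2 libraries, replicates 1 and 2, of pooled caudal tissue from wild-type mouse embryos at embryonic day 8.5, when the trunk is still being laid down from the tail end. The series title concerns neuromesodermal progenitors, caudal cells known to supply both spinal cord and paraxial mesoderm and to express Sox2, a neural progenitor transcription factor, together with T (Brachyury), a mesodermal one. The labels give 1 group, so the comparisons are between cell classes within the tissue. After filtering, replicate 1 held 20930 cells with a median of 9792.5 UMIs and 3035 genes, and replicate 2 held 13225 cells with a median of 9769 UMIs and 3305 genes. Gene levels below are in CPM of counts summed per class and library (n = 2 libraries per class). Values after ± are SE unless SD is named. The labels do not say that the libraries came from separate pools of embryos. With library as a block, p values measure how far class differences disagree between these libraries, by a spread per gene that all classes of a fit share. A gene can therefore pass although the libraries disagree for the small double-positive class. Msgn1 passed against Sox2-only cells with log2 values of 3.54 and 0.18 in replicates 1 and 2. The p values do not measure the spread between the libraries themselves or between embryos.

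The question of which cells the tissue held was addressed by clustering, which gave 27 clusters and 15 named classes. Caudal epiblast-like cells, led by Epha5, Nkx1-2, Hes3, Cyp26a1 and Fgf8, made up 21.1% of replicate 1 and 16.4% of replicate 2 (mean 18.7% ± 3.30 SD, n = 2). Presomitic mesoderm-like cells, led by the Notch ligands Dll1 and Dll3 and the transcription factors Msgn1 and Tbx6, made up 22.0% (95% interval 21.5 to 22.6) and 14.6% (14.0 to 15.3). Neural-like cells, marked by Sox1, Sox3 and Pax6, transcription factors of the neural tube, made up 3.0% (628 cells) and 3.45% (456 cells). Lateral plate mesoderm-like cells with Hand2 and Foxf1 made up 20.5% and 31.0%. Endoderm-like cells (8.17% and 7.52%), surface ectoderm-like cells (8.13% and 7.34%), somite-like cells with Tcf15 and Meox1 (5.46% and 6.46%), endothelium-like cells with Kdr and Cdh5 (4.21% and 4.94%) and allantois-like cells with Tbx4 (3.87% and 2.96%) were found in both libraries. The smaller classes were notochord-like cells with Noto and Shh (0.721% and 0.756%), amnion-like cells (0.764% and 0.340%) and primordial germ cell-like cells (18 and 9 cells). Intermediate mesoderm-like cells numbered 56 and 337, and blood-like cells with Hba-x numbered 7 and 163. Extraembryonic endoderm-like cells with Apoa1 and Ttr numbered 283 in replicate 1 and 0 in replicate 2, which allows a share of up to 0.0279%. No cluster was named primitive streak-like, and 60 and 52 cells stayed unnamed.

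**Figure D1:**
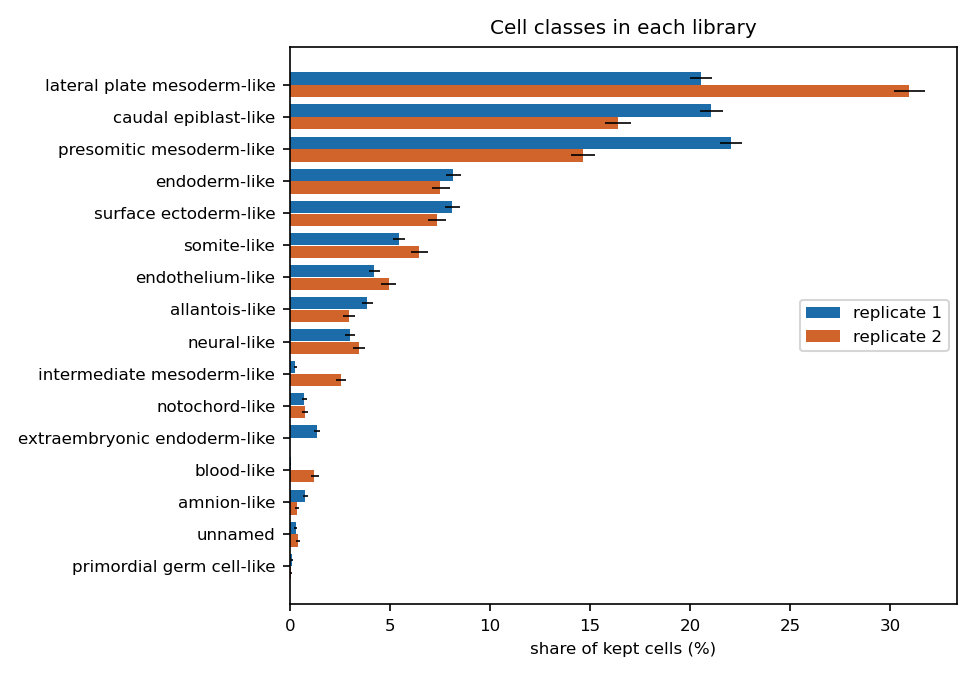
Percent of cells in each named class in replicates 1 and 2, with exact 95% intervals for counting error. Lateral plate mesoderm-like cells ranged from 20.5% to 31.0% and presomitic mesoderm-like cells from 22.0% to 14.6% between the libraries.

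Most classes split into a deep cluster with about 1% mitochondrial UMIs and a shallow one with almost none. Barcodes under 0.3% mitochondrial UMIs made up 51.2% (10725) of the cells of replicate 1 and 39.0% (5160) of replicate 2. Their median depths were 5589 and 4839 UMIs, against 17343 and 13540 in the other cells. Within cell classes, transcripts of endoplasmic reticulum proteins lay at a median of 0.421 and 0.213 times, and those of extracellular matrix proteins at 0.231 and 0.125 times, their level in the other cells. Nuclear-retained RNAs lay at 0.278 and 0.284 times. Transcripts of mitochondrial proteins encoded in the nucleus lay at 1.03 and 0.968 times, whereas ribosomal protein transcripts lay at 1.16 and 1.21 times and glycolysis transcripts at 1.12 and 1.16 times. The neural-like class held 8.28% and 0% such barcodes and was deep, with medians of 19998.5 and 15215.5 UMIs. Clustered alone, however, the barcodes under 0.3% held 451 and 141 neural-like cells, of which 403 and 139 lay in the caudal epiblast-like class above. At resolution 2 the neural-like class made up 5.48% and 4.88% of all cells and held 45.1% and 30.5% such barcodes. The caudal epiblast-like class thus includes low-mitochondrial cells that other clusterings name neural-like.

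**Figure D2:**
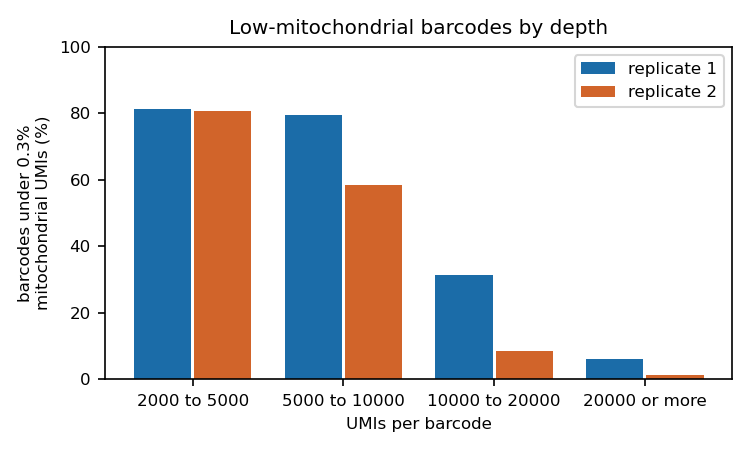
Percent of kept cells with under 0.3% mitochondrial UMIs, by UMI total per barcode, in replicates 1 and 2. At 10000 to 20000 UMIs they made up 31.5% and 8.42% of cells.

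Sox2 and T were found together in few cells, mostly in the caudal epiblast-like class. At 3500 UMIs per cell, caudal epiblast-like cells were double-positive in 36 of 3632 (0.991%, 95% interval 0.695 to 1.37) and 20 of 1742 (1.15%, 0.703 to 1.77). Presomitic mesoderm-like cells were double-positive in 5 of 3852 (0.130%) and 4 of 1565 (0.256%), and neural-like cells in 0 of 628 and 0 of 453, which allows up to 0.586% and 0.811%. The whole compartment held 41 of 8112 (0.505%, 0.363 to 0.685) and 24 of 3760 (0.638%, 0.409 to 0.948). As background, blood-like and endothelium-like cells held 0 of 729 and 0 of 673, which allows up to 0.505% and 0.547%. Thus the caudal epiblast-like share lay above the background limit in each library, whereas the interval of the compartment's share overlapped it. Median depths before thinning were 8578 and 9756 UMIs in the compartment and 10897.5 and 10161 UMIs in the background cells. Thinning left out 1537 and 801 compartment cells and 159 and 143 background cells. T alone was found in 2.74% and 2.97% of background cells and in 1.27% and 0.662% of neural-like cells, so background cells carried T more often than neural-like cells. Sox2 was found in 12.6% and 15.7% of neural-like cells against 0.137% and 0.594% of background cells.

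Detection of T was less frequent in cells with a Sox2 UMI than in cells without one. The odds ratio was 0.506 (95% interval 0.354 to 0.708) and 0.430 (0.267 to 0.665) in the compartment, and 0.477 (0.322 to 0.690) and 0.492 (0.286 to 0.806) within caudal epiblast-like cells. Since that class includes low-mitochondrial cells that other clusterings name neural-like, its odds ratio need not describe 1 cell type. Independent detection would give double-positive shares of 0.873% and 1.26% in the compartment. Without thinning the double-positive share was 3.80% and 4.49%, against 0.225% and 0.368% in background cells, and the odds ratio was 0.865 (0.755 to 0.990) and 0.597 (0.499 to 0.711). Over all kept cells of every class the mean odds ratio was 1.13. Notochord-like cells, which also express T, were double-positive in 6 of 129 (4.65%) and 2 of 90 (2.22%). A UMI count of 0 does not show that a cell lacks a transcript at this depth, so the classes below are detection classes.

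**Figure D3:**
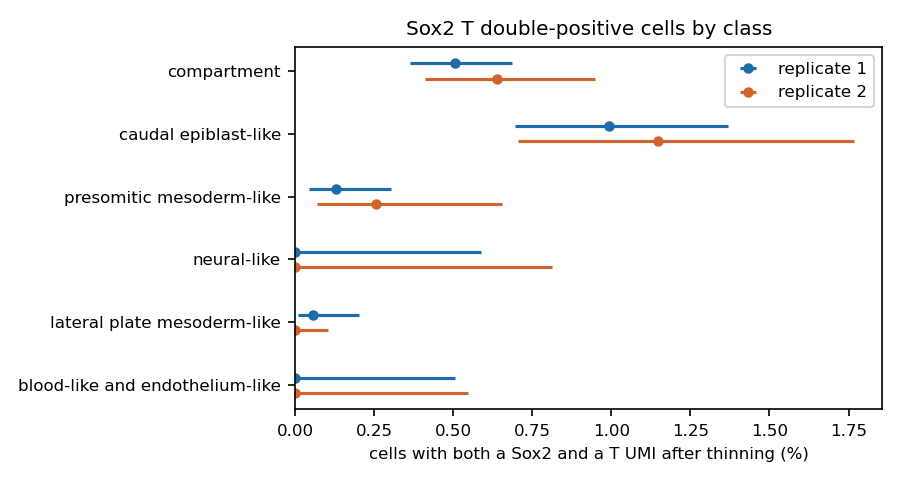
Percent of cells with both Sox2 and T UMIs after thinning to 3500 UMIs, per class and replicate, with exact 95% intervals for counting error. Caudal epiblast-like cells reached 0.991% and 1.15%, and background cells (blood-like and endothelium-like) had 0 such cells.

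The gate gave 41 and 24 double-positive, 282 and 194 Sox2-only, 1738 and 791 T-only and 6051 and 2751 double-negative cells. Caudal epiblast-like cells made up 87.8% and 83.3% of the double-positive class, 67.7% and 62.4% of the Sox2-only class and 55.5% and 50.9% of the T-only class. Neural-like cells made up 28.0% and 36.6% of the Sox2-only class, and presomitic mesoderm-like cells 44.1% and 48.7% of the T-only class. The share of barcodes under 0.3% mitochondrial UMIs was 39.0% and 25.0% in double-positive, 30.5% and 15.5% in Sox2-only and 49.4% and 25.7% in T-only cells. Median depths were 10223 and 15256, 15302.5 and 14924, and 10392.5 and 12302 UMIs in the same order.

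T-only cells differed from Sox2-only cells in transcription factors of the presomitic mesoderm and the neural tube. Some of these genes, such as Tbx6, Msgn1 and Sox1, also mark the presomitic mesoderm-like and neural-like clusters, whose shares differ between the gate classes. No gate fit was run separately by cell class. Differences in these genes and in their lists therefore cannot be told apart from the different shares of those clusters. Msgn1 and Tbx6, transcription factors that specify presomitic mesoderm, were higher in T-only cells by 5.01 ± 0.21 and 4.06 ± 0.12 on the log2 scale. The primitive streak factor Mixl1 (3.76 ± 0.23) and the growth factor Fgf4 (4.47 ± 0.32) were higher too. Transcription factors of the neural tube were lower, among them Rfx4 (-4.47 ± 0.20), Irx1 (-4.46 ± 0.19), Nkx2-9 (-3.66) and Sox1 (-3.56 ± 0.24). Each had the same direction in both libraries, with adjusted p from 5.61e-12 (Tbx6) to 7.2e-08 (Fgf4). In 1 library alone the fold moved by over 1.5 times for Sox1 (log2 -3.85 and -2.87 in replicates 1 and 2) and Fgf4 (4.19 in replicate 1, with 0 CPM in Sox2-only cells of replicate 2). The rule also named Inka1, S1pr3, Arl4d, Uap1l1 and Rnf213 as higher (log2 3.78 to 4.33). Eogt, a glycosyltransferase, was higher by 40.8-fold (counting interval 13.9 to 199, 3 counts in Sox2-only cells). Lower were the cell adhesion gene Nrcam, ccdc198, Pkdcc, the receptor Fgfr2, Fam181a and Cpn1 (-3.14 to -4.07). The libraries were also unequal for Eogt (0 CPM in Sox2-only cells of replicate 1), Uap1l1 (3.37 and 4.83), Nrcam (-3.45 and -4.86), Fam181a (-2.88 and -4.35) and ccdc198 (-3.84 and -4.61). Over all genes, 938 were higher and 918 lower by edgeR, with 3256 at an unadjusted p under 0.05.

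Of 12 presomitic mesoderm genes, 10 were higher in T-only cells and 0 lower (10 and 1 adjusted over the list alone; fry adjusted p = 0.00441; adjusted p = 0.341 with an estimated correlation). Of 17 neural tube genes, 14 were lower and 0 higher (the same counts adjusted over the list alone; 0.0119; adjusted p = 0.341 with an estimated correlation). Of 12 genes of the epithelial to mesenchymal transition, 7 were higher, among them the repressor Snai1 (3.21 ± 0.19, adjusted p = 7.39e-09; 2.78 and 4.19 in the libraries) and fibronectin, Fn1 (1.43), and 1 was lower. That list's fry adjusted p was 0.0119, with an adjusted p = 0.387 with an estimated correlation. Wnt genes were higher in 14 and lower in 6 of 24, FGF genes in 9 and 4 of 20, Notch genes in 7 and 2 of 15, and caudal epiblast genes in 11 and 5 of 19. Cdx2 and Cdx4 were higher among 3 Cdx genes, and Hox groups 1 to 4 had 3 higher and 1 lower of 12. Adjusted over the list alone, these counts were 14 and 8 for Wnt, 12 and 5 for FGF, 7 and 2 for Notch, 11 and 6 for caudal epiblast, 2 and 1 for Cdx and 3 and 1 for Hox genes. The fry adjusted p of these 6 lists lay from 0.0132 to 0.0438, and the adjusted p with an estimated correlation from 0.347 to 0.599. Of 16 BMP and TGF-beta genes 9 were higher and 0 lower (fry adjusted p = 0.112), and of 23 cell cycle genes 1 was higher and 9 lower (0.174). Median, mean and test differed in sign for the somite, epiblast, retinoic acid, glycolysis, endoderm and surface ectoderm lists, none of which passed fry. Without the replicate block, 65 genes were higher and 50 lower.

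Double-positive cells, set against Sox2-only cells, had more Cyp26a1, Wnt3a, Fgf8 and Tbx6 and less Rfx4 and Irx1. Neural-like cells made up 0% of double-positive cells in each library, against 28.0% and 36.6% of Sox2-only cells. Presomitic mesoderm-like cells made up 12.2% and 16.7%, against 4.26% and 1.03%. Without a fit by cell class, differences in neural tube and presomitic mesoderm genes cannot be told apart from these shares. Cyp26a1, the enzyme that degrades retinoic acid at the tail end, was higher by 2.66 ± 0.16 on the log2 scale (341 against 51.7 CPM, adjusted p = 7.61e-08). The Wnt ligand Wnt3a (2.38 ± 0.24, 6.43e-05), the Wnt amplifier Rspo3 (2.33 ± 0.13, 4.3e-08) and the growth factor Fgf8 (2.06 ± 0.12, 7.61e-08) were higher. Tbx6 (2.79 ± 0.29, 7.3e-05) and the cell cycle inhibitor Cdkn1a (2.59 ± 0.31, 0.000321) were higher as well. Each of these was higher in both libraries, Cdkn1a unequally (2.03 and 3.78). Msgn1 was higher by 2.88 ± 0.53 (0.0117), a value that rests on replicate 1 (log2 3.54, against 0.18 in replicate 2). The rule also named Arl4d, Lmo2, Efna1, a ligand of Eph receptors, and Hoxd9 (log2 2.41 to 2.66). Lower were neural tube regulators: Rfx4 by 27.4-fold (counting interval 4.88 to 1088, 1 count in double-positive cells), Nkx2-9 by 17.7-fold (3.13 to 702, 1 count) and Irx1 by 14.9-fold (4.09 to 124, 2 counts). Ptprz1, a receptor phosphatase of neural progenitors, was lower with -3.52 ± 0.48 (0.00094; -3.01 and -4.34 in the libraries). Rfx4, Nkx2-9 and Cpn1 had 0 CPM in double-positive cells of replicate 2, and Irx1 and Thsd4 in those of replicate 1. Pkdcc, Ret and Fam181a had 0 counts in double-positive cells, at least 10.3-, 5.60- and 4.90-fold lower. Thsd4 (16.9-fold, 2.99 to 672) and Cpn1 (17.0-fold, 3.01 to 676) were lower. In all, 84 genes were higher and 70 lower by edgeR, with 1429 at an unadjusted p under 0.05.

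Of 19 caudal epiblast and neuromesodermal progenitor genes, 10 were higher in double-positive than in Sox2-only cells and 2 lower (11 and 2 adjusted over the list alone; fry adjusted p = 0.0302; adjusted p = 0.525 with an estimated correlation). Among them were Epha5 (1.15 ± 0.17, adjusted p = 0.00231), Evx1 (1.48 ± 0.17, 0.000201) and Fgf17 (1.85 ± 0.21, 0.000232), while Hes3 was lower (-1.15 ± 0.25, 0.0336; -0.76 and -1.93 in the libraries) and Nkx1-2 was not past the test (0.10 ± 0.15, 0.868). Of 12 presomitic mesoderm genes 7 were higher and 0 lower (9 and 0 adjusted over the list alone; fry 0.0129; adjusted p = 0.387 with an estimated correlation), including Dll1 (2.27 ± 0.24) and Cited1 (1.98 ± 0.24; 2.42 and 0.96 in the libraries). Of 17 neural tube genes Pax6 (-2.39 ± 0.48, 0.0201) and Sox3 (-1.53 ± 0.29, 0.0146) were lower and 0 higher (12 and 0 adjusted over the list alone; fry 0.00441; adjusted p = 0.387 with an estimated correlation). Their median log2 change was -1.08 with bounds, and 6 of them had 0 counts in a class. Of 24 Wnt genes 9 were higher, such as Wnt5b (1.71 ± 0.21) and Lef1 (0.94 ± 0.15), and 3 lower, such as the Wnt inhibitor Sfrp1 (-1.91 ± 0.41). Adjusted over the list alone these were 12 and 3 (fry 0.0388; adjusted p = 0.531 with an estimated correlation). The fitted mean of the Wnt list was -0.31, opposite to its median of 0.57 and its test, and was 0.44 with bounds. Of 20 FGF genes 6 were higher and 2 lower (9 and 4 adjusted over the list alone; fry 0.0324; adjusted p = 0.538 with an estimated correlation), with Etv4, an FGF-induced factor, at 0.96 ± 0.13. Of 15 Notch genes 4 were higher and 0 lower (5 and 1 adjusted over the list alone; fry 0.036; adjusted p = 0.41 with an estimated correlation). Cdx2 (0.67 ± 0.08, 0.000321) and Cdx4 (0.96 ± 0.07, 1.3e-06), regulators of trunk and tail identity, were higher among 3 Cdx genes (2 and 0 adjusted over the list alone; fry 0.0324; adjusted p = 0.538 with an estimated correlation). Of 12 genes of the epithelial to mesenchymal transition only Vim (0.81 ± 0.17, 0.0235) was higher, with a value of -0.16 in cells of at least 4000 UMIs (3 and 1 adjusted over the list alone; fry 0.0353; adjusted p = 0.538 with an estimated correlation).

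The other lists did not pass fry in double-positive against Sox2-only cells. Retinoic acid genes were higher in 3 and lower in 2 of 14 (fry adjusted p = 0.534), with the retinoic acid-binding gene Crabp2 lower (-0.80 ± 0.15). Hox groups 5 to 9 had 2 higher of 15 (0.412), Hoxd9 and Hoxb6 (1.35 ± 0.19), and Hox groups 10 to 13 had 1 higher of 4 (0.815), Hoxc10, which had 0 CPM in replicate 1 double-positive cells and rests on replicate 2. Hox groups 1 to 4 had 0 higher and 0 lower of 12 (0.0732). Primitive streak genes had 1 higher of 5 (0.533), Fgf4 (4.19 ± 0.64), and surface ectoderm genes had 1 higher of 4 (0.102), the ligand Wnt6 (1.99; 1.74 and 2.67 in the libraries). Cell cycle genes had Cdkn1a higher and the replication gene Mcm5 (-0.45, but 0.016 with doublets retained) lower of 23 (0.245). Glycolysis genes had 2 lower of 16 (0.456), the glucose transporter Slc2a1 (-1.0 ± 0.16) and Gapdh (-0.20). Endoderm genes had Cpn1 lower of 5 (0.346), with a log2 value of 0.41 when cells of every class were gated. Somite (5 genes, 0.0807), epiblast and pluripotency (8, 0.314), epithelial adhesion (11, 0.82), BMP and TGF-beta (16, 0.223), dissociation stress (14, 0.0877), blood (4, 0.828), endothelium (3, 0.777) and lateral plate mesoderm (6, 0.548) had 0 higher and 0 lower. Adjusted over the list alone, epiblast and BMP genes had 3 higher each, and cell cycle genes 1 higher and 5 lower. With bounds, median, mean and test differed in sign for the epithelial adhesion, retinoic acid, dissociation stress and blood lists. The notochord and node list and the neural crest list had fewer than 3 measured members in these classes. Among barcodes under 0.3% mitochondrial UMIs, with 7 double-positive cells, 6 genes passed and Tbx6, Msgn1 and 12 other named genes had the opposite sign. Without the replicate block, 5 genes were higher and 0 lower, and DESeq2 called 177 and 57, a larger share higher than by edgeR. With the expected share of doublets removed, 95 were higher and 162 lower, a smaller share higher.

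**Figure D4:**
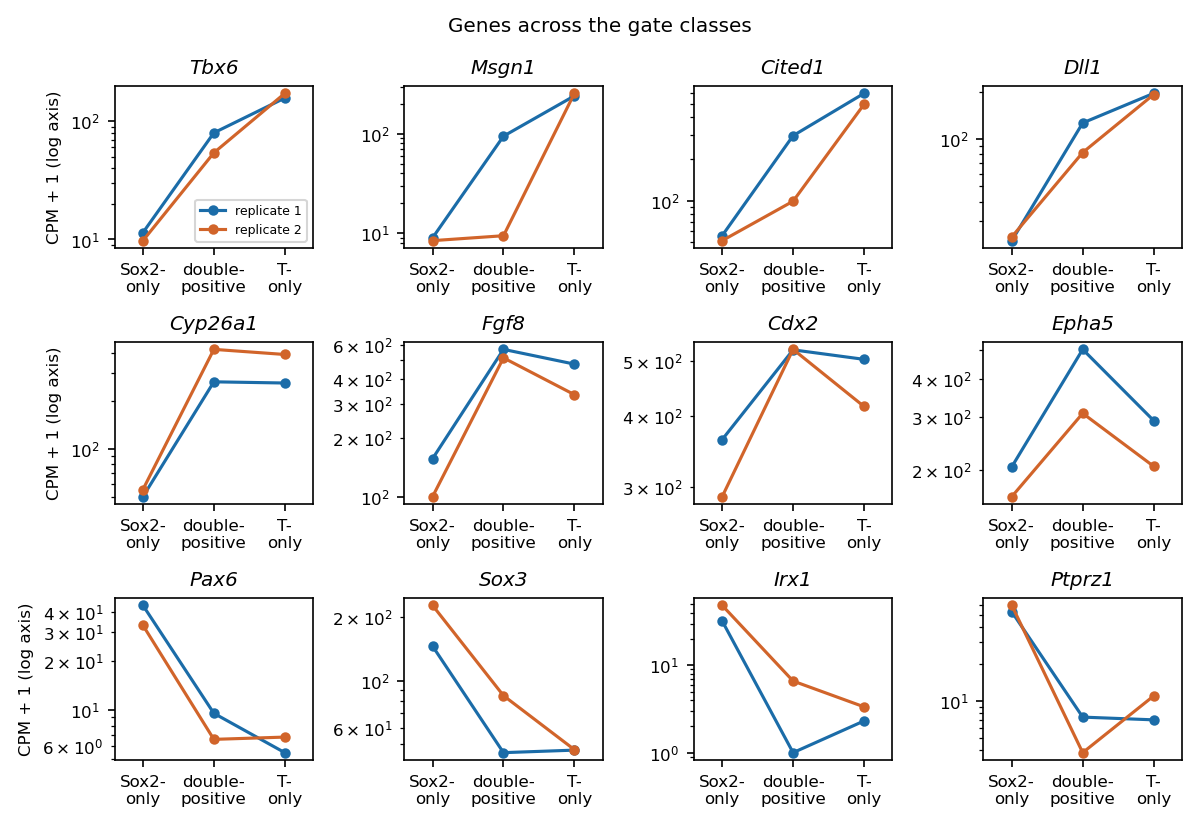
CPM (log axis, 1 added) of 12 genes in Sox2-only, double-positive and T-only cells, 1 line per replicate. Tbx6 was higher in double-positive than in Sox2-only cells (log2 2.79) and lower than in T-only cells (log2 -1.27).

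Against T-only cells, double-positive cells had less of a few presomitic mesoderm transcripts. They also held fewer presomitic mesoderm-like cells, 12.2% and 16.7% against 44.1% and 48.7% of T-only cells. Without a fit by cell class, the lower transcripts cannot be told apart from these shares. Msgn1 (-2.13 ± 0.29, adjusted p = 0.00467), Tbx6 (-1.27 ± 0.18, 0.00467) and Cited1, a transcriptional coactivator (-1.43 ± 0.17, 0.00122), were lower in both libraries, Msgn1 (-1.36 and -4.91) and Cited1 (-1.02 and -2.34) unequally. Also lower were the hormone gene Sct (-2.21 ± 0.33), Inka1 (-1.94 ± 0.33), the imprinted gene Phlda2 (-1.85 ± 0.21), the genome maintenance gene Smc6 (-1.0 ± 0.14), Ifitm2 (-0.54 ± 0.10) and Tmsb10, which sequesters actin (-0.30 ± 0.03). Their adjusted p lay from 0.00104 to 0.0418. By edgeR 0 genes were higher and 10 lower, with 976 at an unadjusted p under 0.05, and DESeq2 called 6 higher and 16 lower. Of 12 presomitic mesoderm genes 3 were lower and 0 higher (6 and 0 adjusted over the list alone; median log2 -0.49 with bounds; fry adjusted p = 0.0233; adjusted p = 0.41 with an estimated correlation). Genes of the epithelial to mesenchymal transition were lower on balance, with 0 of 12 past the test over all genes and 4 lower adjusted over the list alone (median log2 -0.37; fry 0.0132; adjusted p = 0.538 with an estimated correlation). Caudal epiblast genes had 0 past the test and 4 higher adjusted over the list alone (fry 0.229), with Nkx1-2 at 0.82 ± 0.15 (0.0668), Epha5 at 0.72 ± 0.16 (0.129) and Fgf8 at 0.41 ± 0.10 (0.179). In cells with at least 0.3% mitochondrial UMIs, Nkx1-2 (1.13 ± 0.13, 0.000204), Hes3 (1.35 ± 0.23, 0.00566; 0.94 and 1.98 in the libraries) and Sox3 (1.19 ± 0.19, 0.00387) were higher, as they were on unthinned counts (1.14 ± 0.10, 1.54 ± 0.16 and 1.26 ± 0.11; adjusted p = 4.07e-05, 0.00011 and 3.5e-05). Hes3 (0.83 ± 0.30, 0.481) and Sox3 (0.38 ± 0.35, 0.849) were not past the test at 3500 UMIs, and both are named after their values were seen. The neural tube list had 0 past the test (fry 0.068), with a median of 0.20 opposite to the direction of its test. With bounds, signs also differed for the epiblast, retinoic acid, Hox groups 10 to 13, cell cycle and blood lists, and none of the 21 remaining lists passed fry. On unthinned counts 11 of 27 lists passed fry, and 10 of 26 in cells with at least 0.3% mitochondrial UMIs, with 0 past the test with an estimated correlation in either. Without the replicate block 0 genes passed. The count ranged from 0 to 768 over the alternatives, and the balance of directions changed: 358 genes were higher and 410 lower on unthinned counts, 27 and 72 in cells of at least 4000 UMIs, and 25 and 81 in cells with at least 0.3% mitochondrial UMIs.

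Genes higher in double-positive cells than in both single-positive classes would not follow from a mixture of those classes in their whole make-up. A mixture of only their caudal epiblast-like cells could give such genes, so they do not exclude every mixture. By edgeR 0 genes were higher than in both, with 149 at an unadjusted p under 0.05, and 0 were lower than in both, with 296 at an unadjusted p under 0.05. With RLE scaling 0 were higher. DESeq2 called 3 higher, the neuronal gene Crmp1, the ephrin receptor Epha5 and Fgf8, and 2 lower, Rps19 and Cetn3. Crmp1, Rps19 and, below, Rpl8 lie outside the rule and are named after their values were seen. With the expected share of doublets removed 7 were higher and 55 lower, 39 of the latter Rpl and Rps genes of ribosomal proteins. On unthinned counts 47 were higher and 11 lower. Barcodes under 0.3% mitochondrial UMIs then made up 16.6% and 8.78% of double-positive, 26.3% and 14.0% of Sox2-only and 49.1% and 26.2% of T-only cells. Median depths were 19647 and 16785, 18105.5 and 15214, and 10997 and 12233.5 UMIs in the same order. There Epha5 was above Sox2-only cells by 1.38 ± 0.17 and above T-only cells by 0.68 ± 0.16 (adjusted p = 0.00036 and 0.0266), and Tril, a Toll-like receptor accessory gene, by 2.03 ± 0.15 and 0.72 ± 0.12. Id3, a target of BMP signalling, was below them by log2 values of -1.12 ± 0.14 and -0.70 ± 0.14 (0.000329 and 0.00948). Each held in both libraries. Among cells with at least 0.3% mitochondrial UMIs, Cdx2 was above both by 0.87 ± 0.07 and 0.36 ± 0.07 (3.85e-06 and 0.0166). Epha5 was called higher than in both in 10 of 17 alternatives, Fgf8 in 5 and Cdx2 in 4. Id3, Rpl8 and Rps19 were each called lower in 5. All 5 lower genes at resolution 2 and all 7 without centring were Rpl and Rps genes. Epha5 is also a marker that named the caudal epiblast-like class, to which most double-positive cells belonged.

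Whether double-positive cells are graded was asked by setting T-biased against Sox2-biased cells on unthinned counts. There were 195 and 88 T-biased, 38 and 39 Sox2-biased and 134 and 78 tied cells. Higher in T-biased cells were Cyp26a1 (2.25 ± 0.16, adjusted p = 7.66e-08), Cdkn1a (2.08 ± 0.22, 1.75e-05), Wnt3a (1.92 ± 0.26, 0.000502), Tbx6 (1.94 ± 0.29, 0.00105) and Msgn1 (2.39 ± 0.39, 0.0026). The rule also named Arl4d, Lmo2, Efna1, Cdk18 and the junction protein gene Jup (log2 2.11 to 3.17). Lower were the receptor Ret (-2.98 ± 0.47, 0.00186), the homeobox gene Meis2 (-1.46 ± 0.29, 0.0123), the centrosomal gene Nin (-1.41 ± 0.15, 1.22e-05) and Hes3 (-1.20 ± 0.21, 0.00481). Timp3, Sema3e, Zic5, Efnb1, Rgma and Ptn were lower too (log2 -0.93 to -1.47). Each had the same direction in both libraries, but the fold in 1 library moved by over 1.5 times for Msgn1 (log2 1.63 and 5.03 in replicates 1 and 2), Tbx6 (1.36 and 2.93), Jup (1.93 and 3.25), Efna1 (1.92 and 3.04), Lmo2 (3.1 and 1.86) and Cdk18 (2.8 and 1.46). In all, 89 genes were higher and 32 lower by edgeR (82 and 58 by DESeq2).

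Of 12 presomitic mesoderm genes 7 were higher in T-biased cells and 0 lower, with Hes7, a segmentation clock gene, at 1.43 ± 0.14 (the same counts adjusted over the list alone; fry adjusted p = 0.0107; adjusted p = 0.353 with an estimated correlation). Caudal epiblast genes were higher in 8 and lower in 1 of 19, including Fgf8 (1.64 ± 0.13) and Cdx4 (0.52), with 11 and 3 adjusted over the list alone (fry 0.00844). Wnt genes were higher in 8 and lower in 1 of 24 (11 and 2 adjusted over the list alone; fry 0.00592), with Rspo3 at 1.63 ± 0.13. For these and for the Notch (4 higher of 14), Cdx (2 of 3), primitive streak (1 of 4), BMP (0 of 16), dissociation stress (0 of 11) and lateral plate (0 of 7) lists, fry passed and the adjusted p = 0.353 with an estimated correlation. The FGF list (4 higher, 1 lower of 20; fry 0.0278; adjusted p = 0.539 with an estimated correlation) had a median of -0.03, opposite to its test and its mean. The retinoic acid list (2 higher of 14; 0.0162; adjusted p = 0.711 with an estimated correlation) had a mean of -0.06, opposite to its median and its test. Of 18 neural tube genes Sox3 (-0.73 ± 0.16) and Ncam1 (-0.59) were lower and 9 were lower adjusted over the list alone (fry 0.0548). The neural crest list had 0 past the test of 4 (0.679). Neural-like cells made up 2.05% and 0% of T-biased and 13.2% and 7.69% of Sox2-biased cells. No graded fit was run within 1 class. A different share of presomitic mesoderm-like cells between the groups therefore cannot be told apart from a grading of double-positive cells. Barcodes under 0.3% mitochondrial UMIs made up 15.9% and 10.2% of T-biased and 5.26% and 0% of Sox2-biased cells, with median depths of 20057 and 16746 against 21968.5 and 18713 UMIs. Only 7 genes passed without the replicate block.

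Caudal epiblast-like cells were set against neural-like cells on genes that had neither formed nor named the clusters. Higher in caudal epiblast-like cells were Fgf8 (5.5 ± 0.38, adjusted p = 6.13e-07), Fgf17 (4.65 ± 0.16, 9.48e-11), Wnt3a (2.77 ± 0.30, 2.81e-05), and the feedback inhibitors Notum (3.47 ± 0.29, 2.88e-06) and Spry4 (3.33 ± 0.28, 2.79e-06). Cyp26a1 (3.84 ± 0.54, 0.000285) and Cdx4 (2.46 ± 0.31, 9.56e-05) were higher. Neural-like cells had more of the receptors Fgfr2 (-3.54 ± 0.33) and Rarb, a retinoic acid target (-3.27 ± 0.46), of Fgf15 (-2.85 ± 0.51) and of the Wnt repressors Sfrp1 (-2.08 ± 0.26) and Tcf7l1 (-1.72 ± 0.17). Each held in both libraries. In 1 library alone the fold moved by over 1.5 times for Cyp26a1 (log2 2.83 and 5.23 in replicates 1 and 2), Cdx4 (3.11 and 1.93) and Fgf15 (-1.55 and -3.76). Of 94 held-out genes 32 were higher and 13 lower by edgeR (43 and 21 adjusted over the list alone). Barcodes under 0.3% mitochondrial UMIs made up 56.8% and 42.3% of caudal epiblast-like against 8.28% and 0% of neural-like cells. At 0.3% or more 35 of 94 were higher and 16 lower, and under 0.3%, where each side was clustered anew, 34 and 14 of 90. Of 21 FGF genes 12 were higher and 5 lower (13 and 5 adjusted over the list alone; fry adjusted p = 0.00131), and of 24 Wnt genes 11 and 5 (13 and 7 adjusted over the list alone; 0.00441). For both, the adjusted p = 0.341 with an estimated correlation. Hox groups 5 to 9 had 4 higher of 15 (0.0732), among them Hoxd9 (3.64 ± 0.69; 2.69 and 4.14 in the libraries) and Hoxa9 (2.32 ± 0.54; 4.14 and 1.54), Hox groups 1 to 4 had 2 higher and 1 lower of 12 (0.347), and Hox groups 10 to 13 had 0 of 6 (0.102). Retinoic acid genes had 2 higher and 2 lower of 14 (0.907), with a median of -0.42 and a mean of -0.15 opposite to the direction of the test. Without the replicate block 27 genes passed.

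Against presomitic mesoderm-like cells, caudal epiblast-like cells were higher in Fgf8 (1.33 ± 0.28, adjusted p = 0.00468), Fgf17 (1.07 ± 0.13, 3.28e-05), the binding protein gene Fgfbp3 (3.72 ± 0.49, 0.000104) and the ligand Wnt8a (2.68 ± 0.43, 0.000574). They were lower in the Wnt inhibitor Dkk1 (-3.04 ± 0.55, 0.00147), the Wnt effector Lef1 (-1.59 ± 0.19, 3.28e-05), Fgf3 (-2.37 ± 0.46) and Fgf4 (-1.74 ± 0.34). Each had the same direction in both libraries, but the fold in 1 library moved by over 1.5 times for Fgfbp3 (log2 4.57 and 1.81 in replicates 1 and 2), Wnt8a (3.22 and 1.45) and Fgf4 (-1.21 and -2.47). Of 94 held-out genes 10 were higher and 12 lower by edgeR (15 and 17 adjusted over the list alone). Hox groups 10 to 13 had 3 lower of 6 and 0 higher (fry adjusted p = 0.0368; adjusted p = 0.387 with an estimated correlation). Among cells with at least 0.3% mitochondrial UMIs, 0 of the 6 lists passed fry in this comparison. The 3 lower genes were Hoxd11 (-2.10 ± 0.48, 0.00744), Hoxc11, at 0 CPM against 0.490 CPM, and Hoxd13, at 0.18 against 0.82 CPM, the last pair at levels too low for a fold. Wnt genes had 4 higher and 3 lower of 24 (0.516), FGF genes 5 and 4 of 21 (0.559), retinoic acid genes 1 and 0 of 14 (0.529), Hox groups 1 to 4 0 and 2 of 12 (0.323) and Hox groups 5 to 9 0 and 0 of 15 (0.874). The Wnt list's median (0.26) and mean and the median of Hox groups 5 to 9 (0.15) were opposite to their tests. Without the replicate block 5 genes passed.

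Between the libraries, Pearson's r across genes of log2 CPM within a class ran from 0.894 in notochord-like to 0.965 in endothelium-like cells and Spearman's rho from 0.916 to 0.964. Genes that differed in 1 direction in every class were led by Xist, the X-inactivation RNA, at 92.5 CPM in replicate 1 and 0.20 CPM in replicate 2. Xist was found in 5744 of 20930 cells of replicate 1 and in 26 of 13225 cells of replicate 2. The Y-linked genes were found in both libraries and were higher in replicate 2. They were Ddx3y (8.76 and 22.3 CPM), Eif2s3y (22.0 and 36.6 CPM), Kdm5d (3.52 and 14.9 CPM) and Uty (4.5 and 15.9 CPM). Together, the values of Xist and these genes argue against 2 samples of 1 pool of cells. Haemoglobin Hbb-bh1 was at 10.6 and 2269 CPM. The pluripotency factor Pou5f1 (41.3 and 2.53 CPM) and the Nodal pathway factor Foxh1 (36.8 and 5.09 CPM) were higher in replicate 1, whereas the posterior gene Hoxc10 (4.15 and 57.1 CPM) was higher in replicate 2. Gt(ROSA)26Sor (7.26 and 0.53 CPM), Wdfy1 (mean log2 difference over classes 2.93), Apoc2 (4.62), Apob (4.31) and Ttr (3.35) were also higher in replicate 1. BC023719 (-6.81), Gm10260 (-6.05) and H2-Q1 (-3.56) were higher in replicate 2. With 1 library on each side these differences have no test.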

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

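The tests of the low-mitochondrial barcodes and of the differences between the libraries, and the tests of doublets by UMI total alone and of free RNA in caudal epiblast-like cells, were chosen after the results were seen. The other 3 tests, of doublets, of free RNA and of the share of low-mitochondrial barcodes, were chosen before.

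A signal appeared in a feature that no comparison used: eGFP, a custom sequence in the feature list, although the genotype is given as wild type. It had 1090 UMIs in 795 cells of replicate 1 (4.27 CPM) and 497 UMIs in 407 cells of replicate 2 (3.55 CPM). Levels were 21.5 and 14.5 CPM in notochord-like cells, 8.45 and 8.39 CPM in endothelium-like cells and 0.836 and 1.10 CPM in surface ectoderm-like cells.

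The first pattern is genes higher in double-positive cells than in both single-positive classes, of which edgeR called 0 and alternatives up to 47. As written beforehand, the doublet test asked for at least 20 such genes and a ratio of median UMI totals under 1.2. The largest ratio was 1.02 but with 0 genes, so that test decides nothing. In a later test of the ratio alone, its upper bound was 1.2, against 1.5 for doublets. That bound argues against doublets of a Sox2-only and a T-only cell as the source of the whole thinned class. A median cannot exclude doublets among a part of these cells. For the unthinned class, which gave the 47 genes, the ratio was not bounded. For free RNA, the test written beforehand asked that the compartment's share lie above the background limit in both libraries. It did, but by only 0.000683 percentage points in replicate 1, within its counting interval. Free RNA is therefore left open here, by a requirement on that interval which the written test did not hold. Within caudal epiblast-like cells the lower bound of 0.695% lies above the highest background limit of 0.547%. This argues against free RNA of both genes at once as the whole source there. A cell that expresses 1 of the genes and took up free RNA of the other is not covered, since Sox2 was rare in the background cells. The share of low-mitochondrial barcodes could not be tested, because 0 genes were available to be followed, and no biological explanation was tested, since the design has 1 group.

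The second pattern is barcodes with under 0.3% mitochondrial UMIs, present in most cell classes. Low depth as the whole cause is argued against by their share of at least 8.42% among barcodes of 10000 to 20000 UMIs in each library, where under 5% was required. Droplets with free RNA only are not excluded by the marker ratios between the own class and the others (lowest class median 3.26), since these markers named classes formed on the same cells, but they are argued against by genes held out of clustering and naming: of 23 that passed in caudal epiblast-like against presomitic mesoderm-like cells among the other barcodes, 22 kept their direction under 0.3%, with a median log2 change of 1.17 where under 0.5 was expected. A candidate explanation, found and tested on the same data, is pieces of cells that lost nucleus and endoplasmic reticulum with their mitochondria, since the medians of the nuclear, reticulum and matrix lists lay at 0.421 times or less (the reticulum gene Sec61b at 1.14 and 1.22 was not lower), whereas the medians of the ribosomal protein, glycolysis and nuclear-encoded mitochondrial protein lists (the last at 1.03 and 0.968) were about level or higher, although Hspd1 of the last list was lower at 0.459 and 0.494. No biological explanation was tested.

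The third pattern is genes that differ between the libraries in the same direction in every cell class. For Pou5f1 and Hoxc10, free RNA that differs between the libraries, as the source in every class, is argued against by the spread over classes, 19.3-fold and 52.8-fold. The spread does not exclude free RNA in the lowest classes. These were notochord-like cells for Pou5f1 (4.66 CPM in replicate 1) and intermediate mesoderm-like cells for Hoxc10 (2.74 CPM in replicate 2). For the haemoglobin genes, free RNA from blood cells in replicate 2 stays open: Hba-x and Hbb-y over Hbb-bh1 departed at most 1.49 times from their ratio in blood-like cells, where up to 1.5 was expected, but that interval (1.21 to 1.83, Hbb-y in somite-like cells) passes the limit, and 9 of 22 ratios had intervals above 1 and 0 below. A different sex of the pooled embryos as the whole cause is argued against. Only 3 of the 20 genes with the largest difference (Xist, Tsix and S100g) lie on chromosome X or Y. For Xist, lower in replicate 2, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, higher there, a different sex is not argued against. A later embryonic stage in replicate 2 cannot be told apart from other causes: in caudal epiblast-like cells the epiblast list lay at percentile 86.7 of random lists with members going both ways (Pou5f1 4.63, Sall4 -0.56), and Hox groups 10 to 13 at percentile 0 with only 2 genes, while batch, genetic background and free RNA of other genes were not tested.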

How the results depend on the processing

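Among the alternatives, only the restrictions to barcodes with at least and with under 0.3% mitochondrial UMIs were chosen after seeing the data; the graded comparison on unthinned counts and the limits for naming clusters were also set with the data in hand. Of 2084 comparisons of named genes with alternatives, 1755 kept direction and side of the threshold, 263 lost the call, 41 gained one and 25 reversed. The cause was not tested for any change unless stated. Counts of genes in T-only against Sox2-only cells stayed within 1.5 times in 14 of 17 alternatives, in both held-out comparisons in 11 of 12 and 12 of 13, in T-biased against Sox2-biased cells in 11 of 15, but in double-positive against Sox2-only cells in 8 of 17 and against T-only cells in 2 of 17. One library alone allows no test. Since the genes were called on these same libraries, the selection largely fixes their direction in each. The called genes that kept their direction in the remaining library numbered 152 to 153 (double-positive against Sox2-only), 10 (against T-only), 1842 to 1855 (T-only against Sox2-only), 119 to 121 (T-biased), 45 and 22 (caudal epiblast-like against neural-like and presomitic mesoderm-like). Single libraries gave 16.4% to 21.1% for caudal epiblast-like cells, 0.505% to 0.638% for the double-positive share and 0.430 to 0.506 for the odds ratio.

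Without the replicate block, calls fell from 154 to 5 (double-positive against Sox2-only), 10 to 0 (against T-only), 1856 to 115 (T-only against Sox2-only), 45 to 27 and 22 to 5 (held-out genes) and 121 to 7 (T-biased). The 4 counts of double-positive cells (against Sox2-only, against T-only, higher than both, lower than both; 154, 10, 0 and 0) became 234, 22, 3 and 2 with DESeq2, 305, 78, 5 and 5 without a filter on low counts, 257, 180, 7 and 55 with the expected share of doublets removed, 366, 99, 3 and 1 at 4000 UMIs or more, 937, 768, 47 and 11 on unthinned counts (more cells in the class by construction), and 272, 106, 2 and 3 at 0.3% mitochondrial UMIs or more. Under 0.3%, where the double-positive class held only 7 cells, they were 6, 17, 1 and 3. Calls were higher in 84 of 154 genes by edgeR, in 177 of 234 by DESeq2, and in 95 of 257, with 162 lower, when the expected share of doublets was removed. Against T-only cells 0 were higher and 10 lower by edgeR, 358 and 410 on unthinned counts, 27 and 72 at 4000 UMIs or more, and 25 and 81 at 0.3% mitochondrial UMIs or more. Retaining doublets gave 86 and 58 in the first pair. The last 3 counts were 23, 1 and 1 at resolution 0.5, 31, 2 and 5 at resolution 2, 49, 1 and 7 without centring, 65, 5 and 1 with another thinning seed and 34, 1 and 1 over all kept cells. At most 5% mitochondrial UMIs gave 35 against T-only cells and 2 higher than both, and a fit without double-negative cells gave 1 higher than both. T-only against Sox2-only gave 3278 on unthinned counts and 276 under 0.3% mitochondrial UMIs. T-biased against Sox2-biased cells gave 5 with a gate of at least 2 UMIs, 73 over all kept cells and 268 without a filter. Gene lists past fry went from 8 to 11 (unthinned) and 14 (0.3% or more) in double-positive against Sox2-only cells, from 2 to 11 and 10 against T-only cells and from 9 to 17 and 14 in T-only against Sox2-only cells; at 0.3% or more they stayed at 2 in caudal epiblast-like against neural-like and fell from 1 to 0 against presomitic mesoderm-like cells. Of the 22 gene list calls by fry, and of 11 more in T-biased against Sox2-biased cells, 0 held by camera with an estimated correlation.

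The caudal epiblast-like share of 18.7% became 15.0% at 0.3% mitochondrial UMIs or more. The double-positive share of 0.572% became 0.670% with doublets retained, 1.58% at 4000 UMIs or more, 0% with a gate of at least 2 UMIs, 4.15% unthinned, 0.398% over all kept cells, and 1.79% and 0.235% at and under 0.3% mitochondrial UMIs. The odds ratio of 0.468 became 0.373 at 4000 UMIs or more, 0.731 unthinned, 0.545 with another seed, 1.13 over all kept cells, and 0.30 and 0.346 at and under 0.3%. These are means of unequal libraries in some settings. With doublets retained, the double-positive share was 0.443% and 0.898% in replicates 1 and 2. Under 0.3% mitochondrial UMIs it was 0.056% and 0.415%, and the odds ratio was 0.097 and 0.595. The thinning depth changes with these filters by construction.

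Under 0.3% mitochondrial UMIs these log2 values against Sox2-only cells reversed, on 7 double-positive cells: Arl4d -6.39, Cdkn1a -0.11, Dll1 -8.36, Epha5 -8.78, Etv4 -0.041, Hoxb6 -1.81, Hoxc10 -0.58, Lef1 -1.21, Lmo2 -8.52, Msgn1 -9.48, Tbx6 -0.81, Vim -1.08, Wnt5b -9.20 and Wnt6 -7.64. Values under -6 come from 0 counts and are no bound. There, Sct reversed against T-only cells (1.2), and Hoxd11 (0.33) and Hoxc11 (0.082) against presomitic mesoderm-like cells. Vim also reversed at 4000 UMIs or more (-0.16) and over all kept cells (-0.27), Cpn1 over all kept cells (0.41) and Mcm5 with doublets retained (0.016). With a gate of at least 2 UMIs, Arl4d (-1.42), Ptn (0.42), Rgma (0.46) and Zic5 (0.50) reversed in T-biased against Sox2-biased cells.

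A gate of at least 2 UMIs left 0 double-positive cells after thinning, so no gate fit or odds ratio could be had. Without centring the neural-like class held 1004 cells in replicate 1 and 3 in replicate 2, so it had no fit. The thinned split had 0 Sox2-biased cells in replicate 1, and cells under 0.3% allowed no graded fit. Depth limits how many cells enter the double-positive class (65 thinned, more when unthinned). At that size simulations recovered 29.9% of 2-fold and 60.9% of 4-fold changes against Sox2-only cells, and 43.4% of genes simulated as higher than in both classes. Depth was not varied in them. With 1 common dispersion and no difference between Sox2-only and T-only cells, these shares need not hold for the data.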

Other observations

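No test in this part was planned beyond the comparisons above, and it gives values only. Notochord-like cells carried both T and Sox2 UMIs in 6 of 129 and 2 of 90 cells after thinning, a higher share than caudal epiblast-like cells in each library, and endoderm-like cells did so in 4 (0.283%) and 6 (0.683%) cells. Pou5f1, a pluripotency factor, was found in 28.6% of cells of replicate 1 and 0.998% of replicate 2, and in caudal epiblast-like cells it lay at 89.9 and 2.67 CPM. In the same class Hoxa10 lay at 0.502 and 21.1 CPM and Hoxc10 at 0.293 and 54.0 CPM, whereas the growth regulators Lin28a (386 and 374 CPM) and Lin28b (47.8 and 43.6 CPM) were close.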
